A study of Homo sapiens with 6 samples.

How the data were processed

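RNA-seq libraries were compared from Ishikawa cells, a human endometrial cancer cell line, taken 48 hours after lipofection with a control siRNA (siNC, 3 libraries) or with an siRNA against TCF19 (siTCF19, 3 libraries). Per the labels' protocols, the cells were grown in DMEM with serum, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. The labels give each library its group and a replicate number, and they name no day, batch or culture behind the numbers.

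The authors deposited 1 table of 58735 genes with, per the file headers, whole-number read counts and FPKM values for each of the 6 libraries, and every one of these columns was matched to its library by name. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3 on the human genome build hg38. The strand setting of the counting and its treatment of reads that match several places are not given in the sources used here. All 58735 gene identifiers, starts and ends in the table equalled those of GENCODE release 29 (Ensembl release 94), tested on the table, and coordinates are given on hg38. The table stored 27 gene symbols as dates, which were replaced through the gene identifier. The deposited FPKM values equalled the count divided by gene length and by 1 library size per library, with a largest relative deviation of 2.8e-09, and that library size was 0.974 to 1.034 times the summed count. The authors' table also holds, per the file headers, a normalized mean signal per group, a log2 fold change, a p-value and an adjusted p-value for each gene. The tool behind those columns is not given in the sources used here, and 13900 genes are listed there with an adjusted p of 1.

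The counts were tested as deposited. Library totals ran from 14680022 to 16244705 counts. Genes were kept by edgeR's filterByExpr, which left 17299 genes that held at least 99.7% of the counts of every library. Counts were scaled by TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, in R 4.3.3) with the group as the only term, and p-values were adjusted by Benjamini and Hochberg. A gene was called at an adjusted p under 0.05, and a 2-fold change was a log2 fold change of at least 1 in size. CPM values use TMM-scaled library sizes, errors on them are SDs over 3 libraries, errors on log2 fold changes are standard errors, and intervals of folds are 95% intervals from those errors. A floor of 3 counts equals 0.185 to 0.204 CPM in these libraries, and intervals and floors cover the errors named only, since PCR copies of a molecule cannot be recognised in a count table. All adjusted p-values of single genes are edgeR's unless another tool is named.

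The gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, except where a test is said to have been chosen afterwards. There were 39 gene lists, of which 36 had the 5 or more tested members that a list test needed. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, on the log2 CPM values with a prior count of 2, adjusted over the 36 lists. Camera compares a list with all other tested genes. The alternatives to it were camera with the correlation estimated per list, and fry, whose p tests whether the genes of a list move, on balance, one way without comparing them with other genes. The rule for named genes took TCF19, then the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between the groups, then the 5 genes with the lowest p in each direction at that level, then up to 4 called members of each list by lowest p (or, where none was called, the 2 members with the highest mean CPM), and then 8 genes set in advance: CCHCR1 and POU5F1 beside TCF19, and CCND1, CCNE1, CDKN1A, MYC, MKI67 and PCNA. The rule named 160 genes, and some of them are not reported here. Members that moved against the call of their list are also named, and these were chosen after their values were seen.

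The alternatives tried were RLE, upper-quartile and library-size-only scaling, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), the replicate number as a block, protein-coding genes only, an adjusted p under 0.01, and each library left out in turn. Added after seeing the data were a run without genes that carry either of 2 short sequences in the 3' UTR, and a run of the list tests after a smooth trend of the fold change over gene length and mean expression (mgcv 1.9.3) was removed. All 7-base words of annotated 3' UTRs, 15864 words over 13256 protein-coding genes with a UTR of at least 50 bases, were also related to the log2 fold change by regression, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

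The steps were tested on simulated data: counts for the same 17299 genes with 200 of them changed, in 5 simulations of the comparison of siTCF19 with siNC. The changed genes were drawn only from genes above a minimum mean count, so recovery in the lowest genes was not tested. The edgeR test recovered 52.4% of genes changed by 1.25-fold, 76.8% at 1.5-fold, 95.2% at 2-fold and 100% at 4-fold, and 6.03% of its calls were unchanged genes. DESeq2 recovered 91.2% at 2-fold with 2.25% false calls, limma-voom 94.4% with 5.18% and limma-trend on log2(FPKM + 1) 84.4% with 5.14%. Camera called a shifted list in 5 of 5 simulations, with every member shifted by -0.3 on the log2 scale. Simulated genes varied independently of each other, so this does not test the preset correlation. The word regression ranked a planted word first in 20 of 20 simulations on 13256 genes, and a word passed the Bonferroni limit in 1 of 20 data sets with permuted fold changes. The planted effect was -0.5 on the log2 scale, larger than the -0.17 of GGTCAAA, the word tied most strongly to lower expression. Recovery at that smaller size was not tested.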

Results

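Gene expression was measured by RNA-seq in Ishikawa cells 48 hours after transfection with a control siRNA (siNC) or an siRNA against TCF19 (siTCF19), with 3 libraries in each group. The siNC libraries held 14872698, 16244705 and 15815632 counts and the siTCF19 libraries 15529688, 14680022 and 15239315. The submitters describe experimental triplicates, and nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within counting noise: the chi-square of their counts per degree of freedom was 2.29 to 3.78 within a group and 25.9 to 30.4 between groups. The first principal component of log2 CPM held 58.3% of the variance and separated siNC from siTCF19. Mitochondrial transcripts took 3.49% to 3.65% of the counts in siNC and 3.92% to 4.08% in siTCF19, and the mitochondrial ribosomal RNAs took 0.283% to 0.344% and 0.581% to 0.642%.

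The comparison asks which transcripts differ when TCF19 is knocked down in endometrial cancer cells. TCF19 itself, a gene with a forkhead-associated domain and a PHD finger (ENSG00000137310, chromosome 6, 31158542 to 31167159, plus strand), was lower in every siTCF19 library. Its counts were 2572, 2905 and 2756 in siNC and 675, 529 and 606 in siTCF19, or 179 ± 4.68 CPM against 39.0 ± 3.69 CPM (SD, n = 3 per group). TCF19 fell 4.59-fold (95% interval 4.23 to 4.99), a log2 fold change of -2.20 ± 0.06 (SE), with an edgeR adjusted p of 6.15e-29. The authors' deposited table lists a log2 fold change of -2.20 for the same gene in the same libraries. Of its neighbours in the HLA class I region, CCHCR1 had a log2 fold change of 0.14 (adjusted p = 0.066) and POU5F1 of -0.37 (adjusted p = 0.14), and neither was called. CCHCR1 was called with library-size-only scaling (log2 fold change 0.20, adjusted p = 0.00729) and without siTCF19 replicate 2 (0.17, adjusted p = 0.0268). Of the 6 tested neighbours in the list, DDR1, a collagen receptor, rose by 0.52 on the log2 scale and 5 were not called, with 1 rise and 0 falls also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.473).

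**Figure D1:**
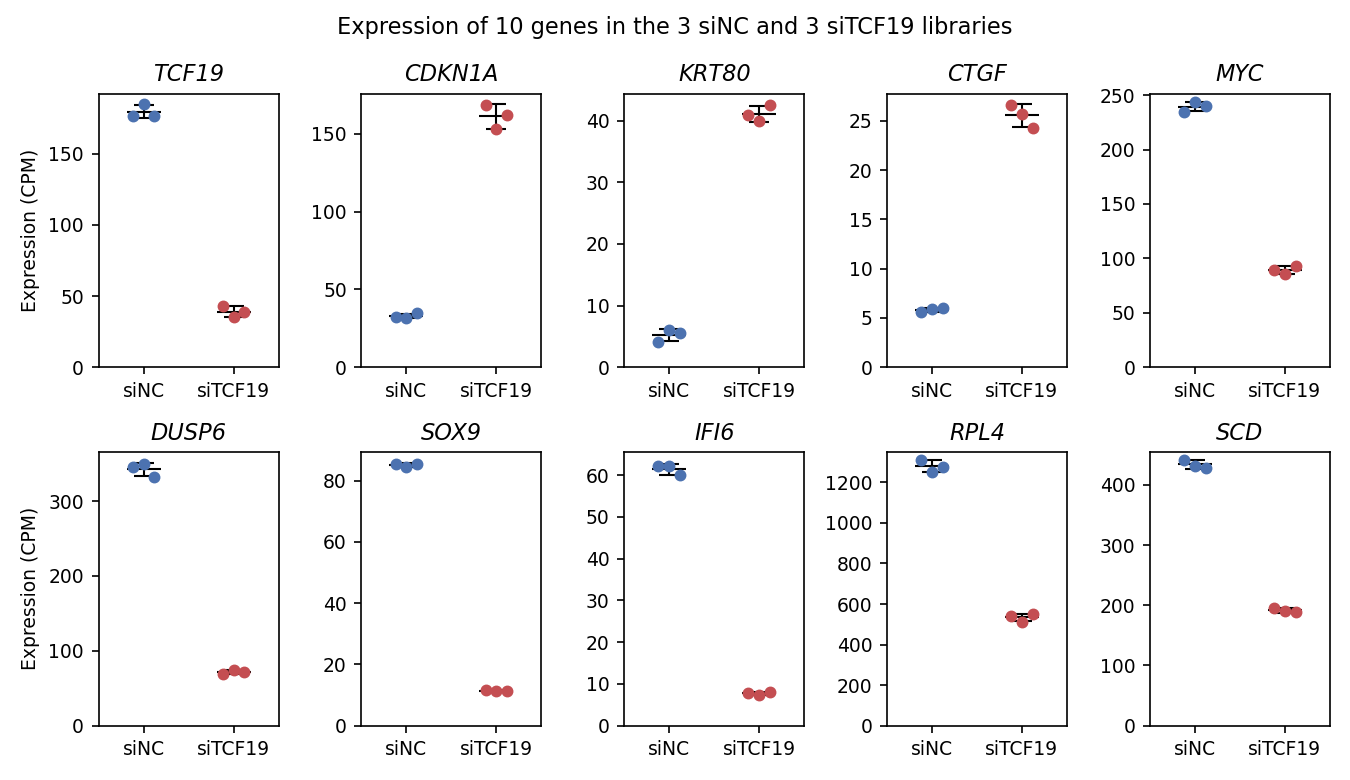
Expression of 10 named genes in each library, in CPM on axes that start at 0, for siNC and siTCF19. Dots are the 3 libraries of a group, bars their mean and error bars the SD. TCF19 lay at 179 CPM in siNC and 39.0 CPM in siTCF19, and CDKN1A at 32.9 CPM and 161 CPM.

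The cyclin-dependent kinase inhibitor CDKN1A rose from 32.9 ± 1.47 to 161 ± 7.89 CPM (SD, n = 3 per group), and the keratin gene KRT80 rose from 5.21 to 41.1 CPM. The transcription factor SOX9 fell from 85.1 to 11.4 CPM, the ERK phosphatase DUSP6 from 343 to 71.8 CPM and MYC from 239 to 89.4 CPM. In all, 3586 genes were higher and 3597 lower in siTCF19 among 17299 tested genes, 41.5% of them, and 464 rose and 375 fell by at least 2-fold. Most of the differences were small: 71.6% of the called genes changed by less than 1.5-fold. In 8517 genes (49.2%) all libraries of one group lay above all of the other, where chance alone gives 10%. The authors' deposited table lists 5737 genes at an adjusted p under 0.05, and the 5702 of them also called here all had the same sign. Its values rest on the same libraries, so this is no separate check. Higher genes were 49.92% of the calls, and 61.35% with library-size-only scaling, which moved the median log2 fold change of all genes from 0.00 to 0.06. On the log2(FPKM + 1) scale, which understates the change of low genes, 83 genes rose and 121 fell by at least 2-fold.

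Ranked here are called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups. Among these, the genes with the largest rises were KRT80 (log2 fold change 2.97), PHLDA3 (2.81), IGFBP7 (2.78), NEBL (2.57), THBS1 (2.38), FOLH1 (2.38), CDKN1A (2.29), DOK7 (2.25), GPNMB (2.21) and TIMP2 (2.20). Thrombospondin 1 is encoded by THBS1, and TIMP2 inhibits matrix metalloproteinases. GPNMB, a transmembrane glycoprotein, rose from 14.3 ± 0.59 to 66.2 ± 2.3 CPM, and MXRA5, a matrix remodelling gene with a low p, from 37.5 to 141 CPM. Under the same limits, the largest falls were in FRG2 (-4.05), SLCO2B1 (-3.91), S100A9 (-3.71), RASD1 (-3.16), SAMD9 (-3.09), IFI6 (-2.99), ALDH3A1 (-2.93), SOX9 (-2.89), SDK2 (-2.82) and IFI27 (-2.76). The organic anion transporter gene SLCO2B1 fell from 19.9 to 1.33 CPM and the RAS-related gene RASD1 from 37.8 to 4.22 CPM. PPP1R1B, which encodes a protein phosphatase inhibitor, fell from 318 to 64.4 CPM, and WASF1, an actin regulator, from 179 to 43.9 CPM. FRG2 has near-identical copies elsewhere in the genome, so its value is uncertain. On the log2(FPKM + 1) scale the values were over 1.5 times nearer 0 for NEBL (0.61), THBS1 (1.03), FOLH1 (1.34), TIMP2 (1.31), SLCO2B1 (-1.37), SAMD9 (-1.12), ALDH3A1 (-1.42) and SDK2 (-0.87), as for 21 of the 156 called named genes. The 3' UTRs of 22 named genes carry TGGTCAA or GGTCAAA, words whose carriers lay lower in siTCF19 than other genes: WASF1 carries both, as TGGTCAAA, RASD1 carries GGTCAAA and the higher gene KRT80 carries TGGTCAA.

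**Figure D2:**
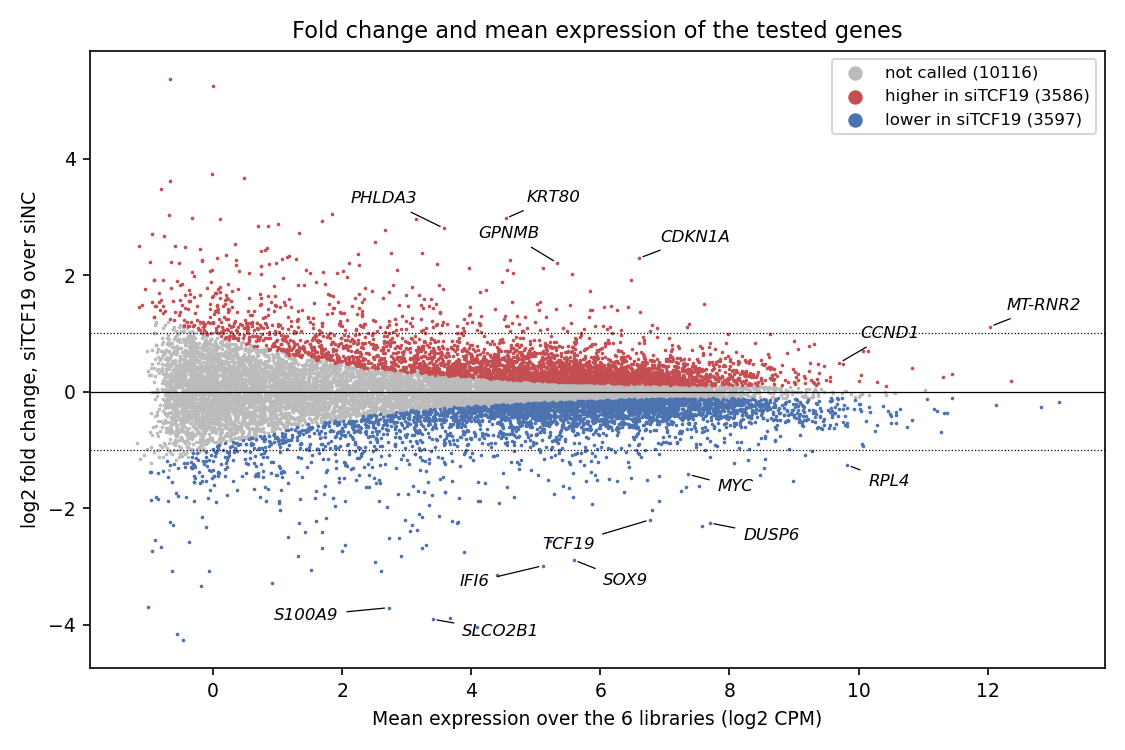
Log2 fold change of siTCF19 over siNC (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 17299 tested genes. Red points are the 3586 called higher, blue the 3597 called lower and grey those not called, and dotted lines mark 2-fold changes.

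Of 36 gene lists tested, 5 were called higher and 9 lower. The higher lists were YAP-TEAD targets, autophagy and lysosome genes, replication-dependent histones, p53 targets and antigen presentation, and the lower ones included ribosomal protein genes, interferon-stimulated genes and genes of glycolysis and lipid synthesis. Camera with an estimated correlation called 0 lists higher (1 at an unadjusted p under 0.05) and 1 lower, the interferon-stimulated genes, while fry called 12 higher and 15 lower, among them 13 of the 22 lists that camera did not call. Of those 13, fry called higher the G1 cyclin, apoptosis, unfolded protein response, mitochondrially encoded, mesenchymal, TGF-beta and squamous lists. It called lower the DNA replication, NF-kB, gluconeogenesis, WNT, cilium and small RNA machinery lists. Ranges of a list's adjusted p are over its camera runs and leave out fry, which compares a list with no other genes. The number of higher lists was 2 without siNC replicate 2, without siTCF19 replicate 1 or without siTCF19 replicate 3, 3 with library-size-only scaling or with no filter, and 2 at an adjusted p under 0.01. Where a list tested with camera had 0 members rising or falling by edgeR, the count was also 0 at an unadjusted p under 0.05 and by DESeq2.

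Genes regulated by the transcriptional coactivator YAP were called higher as a list: 13 of 21 rose, 3 fell and 5 were not called, or 15 and 3 adjusted over the list alone, with a median log2 fold change of 0.47 (camera adjusted p = 0.000282). CYR61, a matricellular protein gene, rose from 101 to 288 CPM, CTGF from 5.84 to 25.6 CPM and FSTL1 from 37.9 to 82.7 CPM. The growth factor gene TGFB2, which carries TGGTCAAA in its 3' UTR, fell by 1.22 on the log2 scale, and DLC1 (-1.04) and ARHGEF17 (-0.23) also fell. YAP-TEAD targets had an adjusted p = 0.194 with an estimated correlation, in a range of 1.77e-06 to 0.194. Of 28 autophagy and lysosome genes, 16 rose, 3 fell and 9 were not called, or 17 and 3 adjusted over the list alone (median 0.22, camera adjusted p = 0.000957). The cargo receptor gene SQSTM1 rose from 259 to 375 CPM, and the lysosomal membrane genes LAMP1 and LAMP2 rose by 0.52 and 0.53. LAMP2 carries TGGTCAA in its 3' UTR. The autophagy genes ATG7 (-0.43) and ATG16L1 (-0.23) and the lysosomal transcription factor TFEB (-0.34) fell. This list had an adjusted p = 0.298 with an estimated correlation, in a range of 0.000186 to 0.298.

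Among 29 p53 targets, 15 rose, 5 fell and 9 were not called, the same counts as adjusted over the list alone (median 0.19, camera adjusted p = 0.0237). CDKN1A and PHLDA3 rose most, PHLDA3 from 2.97 to 20.9 CPM, and the antiproliferative gene BTG2 rose by 1.48. RRM2B (-0.65), a ribonucleotide reductase subunit whose 3' UTR carries TGGTCAA, fell, as did GDF15 (-0.60), FBXW7 (-0.29), the death receptor gene FAS (-0.23) and CCNG1 (-0.22). The list had an adjusted p = 0.327 with an estimated correlation, in a range of 0.0108 to 0.327, and was not called without siNC replicate 2 (0.0811), siTCF19 replicate 1 (0.0715) or siTCF19 replicate 3 (0.0875). Of 8 replication-dependent histones tested among 17, 6 rose, 1 fell and 1 was not called, or 7 and 1 adjusted over the list alone (median 0.49, camera adjusted p = 0.0237). HIST1H2BD rose by 1.05, HIST1H2BC by 1.08 and HIST1H1C by 0.54, while HIST1H1E (-0.90) fell, a call not made by DESeq2 (adjusted p = 0.0569). These genes have close copies and many of their transcripts lack a poly(A) tail, so their values are uncertain. The histone list had an adjusted p = 0.298 with an estimated correlation, in a range of 0.0102 to 0.298, and was not called with library-size-only scaling (0.0507), with no filter (0.0622), without the 3' UTR word carriers (0.0528), or without siNC replicate 2 (0.0811), siTCF19 replicate 1 (0.0812), siTCF19 replicate 2 (0.0881) or siTCF19 replicate 3 (0.0766).

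Interferon-stimulated genes fell together: 24 of 37 fell, 0 rose and 13 were not called, or 25 and 0 adjusted over the list alone, with a median log2 fold change of -0.86 (camera adjusted p = 4.13e-11). IFI6 fell from 61.4 ± 1.31 to 7.73 ± 0.42 CPM, the ubiquitin-like modifier gene ISG15 from 93.0 to 24.3 CPM and IFI27 from 25.7 to 3.81 CPM. This call held with an estimated correlation (adjusted p = 0.0437), in a range of 7.06e-16 to 0.0437. Of its 37 members, 3 carry GGTCAAA in the 3' UTR and 4 carry GGTCAAA or TGGTCAA. Antigen presentation genes, many of them also interferon-induced, went the other way: of 10 tested among 20, 6 rose, 1 fell and 3 were not called, the same counts as adjusted over the list alone (median 0.43, camera adjusted p = 0.0295). B2M, the light chain of HLA class I, rose from 212 to 339 CPM and CD74 by 0.60, while HLA-E fell (-0.36), and HLA values are uncertain because alleles differ from the reference. The peptidase gene ERAP1 rose by 1.20, or 0.78 on the log2(FPKM + 1) scale. The list had an adjusted p = 0.327 with an estimated correlation, in a range of 0.0102 to 0.327, and was not called with library-size-only scaling (0.0634), with no filter (0.278), or without siNC replicate 1 (0.0877), siNC replicate 2 (0.056), siTCF19 replicate 1 (0.0715) or siTCF19 replicate 3 (0.0546). Of 16 NF-kB and inflammatory genes, 1 rose, 5 fell and 10 were not called, the same as adjusted over the list alone (camera adjusted p = 0.284), with falls in TNFAIP2 (-0.55) and NFKBIA (-0.38).

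Ribosomal protein genes were lower almost throughout: 36 of 41 fell, 0 rose and 5 were not called, the same counts as adjusted over the list alone, with a median log2 fold change of -0.38 (camera adjusted p = 3.07e-12). RPL4 fell from 1279 ± 29.03 to 535 ± 18.5 CPM, RPL10A from 536 to 302 CPM and RPL3 from 1509 to 947 CPM. RPL4 carries TGGTCAA in its 3' UTR, and ribosomal protein genes have many processed pseudogenes that can share their reads. Ribosomal protein genes had an adjusted p = 0.377 with an estimated correlation, in a range of 1.74e-16 to 0.377. The hosts of small nucleolar RNAs, whose transcripts share a 5' terminal oligopyrimidine start with ribosomal protein mRNAs, fell in 12 of 13 cases with 0 rises and 1 not called, or 13 and 0 adjusted over the list alone (median -0.45, camera adjusted p = 4.23e-06). SNHG5 (-0.68), GAS5 (-0.62) and SNHG15 (-0.74) fell, as did EPB41L4A-AS1 (-0.91), an antisense gene whose reads cannot be told from those of its partner without the strand setting. This list had an adjusted p = 0.298 with an estimated correlation, in a range of 2.05e-08 to 0.298.

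The glycolysis, fatty acid and cholesterol lists were called lower. Of 23 glycolysis genes, 16 fell, 1 rose and 6 were not called, or 18 and 1 adjusted over the list alone (median -0.24, camera adjusted p = 0.000103). PFKFB3, a regulator of phosphofructokinase, fell from 135 to 61.8 CPM and hexokinase 2 (HK2) from 130 to 62.7 CPM, LDHA fell by 0.61 on the log2 scale, while the enolase gene ENO2 rose (0.67). Glycolysis had an adjusted p = 0.327 with an estimated correlation, in a range of 4.85e-06 to 0.327. Of 16 fatty acid synthesis genes, 10 fell, 3 rose and 3 were not called, the same as adjusted over the list alone (median -0.29, camera adjusted p = 0.0065). FASN fell from 1410 ± 84.4 to 740 ± 11.6 CPM, the lipogenic transcription factor gene SREBF1 from 283 to 130 CPM and the desaturase gene SCD, whose 3' UTR carries GGTCAAA, from 434 to 192 CPM, while THRSP (1.09), ELOVL6 (0.27) and LPIN1 (0.20) rose. Of 24 cholesterol synthesis and uptake genes, 15 fell, 2 rose and 7 were not called, or 16 and 2 adjusted over the list alone (median -0.27, camera adjusted p = 0.00227). The synthesis enzyme genes HMGCS1 (-0.54) and DHCR7 (-0.41) fell, and PMVK (0.54) and SC5D (0.40) rose. Both lipid lists had an adjusted p = 0.298 with an estimated correlation, in ranges of 0.000696 to 0.298 and 0.000186 to 0.298. Of 12 gluconeogenesis genes, 6 fell, 1 rose and 5 were not called, the same as adjusted over the list alone (camera adjusted p = 0.341), among them PCK2 (-0.45) and GOT1 (-0.56), which carries GGTCAAA.

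Of 40 nuclear-encoded oxidative phosphorylation genes, 17 fell, 1 rose and 22 were not called, or 17 and 2 adjusted over the list alone (median -0.10, camera adjusted p = 0.0155). The ATP synthase subunit genes ATP5F1B (-0.54), ATP5F1A (-0.58) and ATP5MC3 (-0.42, a carrier of TGGTCAAA) fell, and NDUFA4 rose (0.21). The list had an adjusted p = 0.402 with an estimated correlation, in a range of 0.00304 to 0.402, and was not called with library-size-only scaling (0.0542), without siTCF19 replicate 2 (0.0881) or with the length and expression trend removed (0.305). Of 15 mitochondrially encoded transcripts, 8 rose, 5 fell and 2 were not called, the same as adjusted over the list alone (camera adjusted p = 0.435), while the share of mitochondrial counts was 3.49% to 3.65% in siNC and 3.92% to 4.08% in siTCF19. The large ribosomal RNA MT-RNR2 rose from 2651 to 5747 CPM, and MT-CO3 fell by 0.37 on the log2 scale. MT-ND6, on the other strand, rose by 0.43, and nuclear copies of mitochondrial DNA and the unstated strand setting leave these values uncertain. MT-ATP6 (-0.33) fell, a call not made on the log2(FPKM + 1) scale (adjusted p = 0.0503).

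Growth factor signalling targets moved in both directions. Of 25 immediate early and MAPK feedback genes, 13 fell, 6 rose and 6 were not called, the same as adjusted over the list alone (median -0.22, camera adjusted p = 0.00747). DUSP6 (-2.25) and SPRY2 (-1.65), which restrain this pathway, and MYC (-1.42) fell, and SPRY4 fell from 263 to 132 CPM. DUSP4 (0.94), EPHA4 (0.93), ATF3 (0.86), FOSL1 (0.74), CCND1 (0.50) and SPRED2 (0.34) rose, and DUSP4 and SPRED2 restrain the same pathway. The list had an adjusted p = 0.298 with an estimated correlation, in a range of 0.000904 to 0.298. Of 18 TGF-beta and SMAD targets, 9 rose, 5 fell and 4 were not called, the same as adjusted over the list alone (camera adjusted p = 0.358). SMAD6 (1.46) and ID1 (0.99) rose, and the receptor gene TGFBR1 (-1.04), which carries TGGTCAAA, fell. Of 16 WNT target genes, 7 rose, 5 fell and 4 were not called, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.883), with LGR5 falling from 63.7 to 10.7 CPM. The median of this list was 0.22, its mean -0.31 and the direction of the test lower. Of 28 PI3K-AKT-FOXO genes, 9 rose, 5 fell and 14 were not called, the same as adjusted over the list alone (camera adjusted p = 0.376, direction higher), with a median of 0.07 and a mean of -0.01. Among these, TXNIP (0.56) and SESN3 (0.57) rose and PIK3R3 (-0.68) fell.

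Cell cycle genes moved in both directions. Of 49 DNA replication and G1/S genes, 20 fell, 9 rose and 20 were not called, or 21 and 9 adjusted over the list alone. The helicase subunit genes MCM7 (-0.52) and MCM3 (-0.37) fell, cyclin E1 (CCNE1, 0.45) rose and PCNA (-0.21) fell. The list was not called (camera adjusted p = 0.0787) but was with no filter (0.0408), in a range of 0.0408 to 0.379, and by fry (adjusted p = 0.00302). Of 54 G2/M and mitosis genes, 16 fell, 9 rose and 29 were not called, or 16 and 10 adjusted over the list alone (camera adjusted p = 0.511), with a median of -0.02 that is 0.04 with library-size-only scaling. MAD2L1 (-0.86), a spindle checkpoint gene that carries TGGTCAAA, and CDC20 (-0.33) fell and TOP2A (0.27) rose. MKI67 (-0.15, adjusted p = 0.0026) fell, a call not made with library-size-only scaling (-0.09, adjusted p = 0.0568). Of 16 G1 cyclins, kinases and inhibitors, 9 rose, 3 fell and 4 were not called, the same as adjusted over the list alone (camera adjusted p = 0.132), CCND1 rising from 692 to 976 CPM and CDKN2A falling by 0.41 on the log2 scale. That list was called with the length and expression trend removed (0.0471), in a range of 0.0471 to 0.327, and by fry (adjusted p = 0.000745).

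Genes of DNA repair, apoptosis and protein folding were not called as lists by camera, while fry called the apoptosis list higher (adjusted p = 0.00122). Of 31 DNA damage repair genes, 7 rose, 3 fell and 21 were not called, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.30), with falls in PARP1 (-0.46) and in MSH6 (-0.28), a carrier of TGGTCAAA, and a rise in BRCA2 (0.30). Of 27 apoptosis regulators, 13 rose, 6 fell and 8 were not called, the same as adjusted over the list alone (camera adjusted p = 0.0784), with rises in the pro-apoptotic BMF (1.16, a carrier of TGGTCAA) and BCL2L11 (0.52) and in the anti-apoptotic BCL2L1 (0.62). Of 26 unfolded protein response genes, 13 rose, 6 fell and 7 were not called, the same as adjusted over the list alone (camera adjusted p = 0.318), and the list was called with the length and expression trend removed (0.0413), in a range of 0.0413 to 0.433, and by fry (adjusted p = 0.00161). The transcription factor gene ATF4 fell from 311 to 171 CPM, and DNAJC3 (0.38) and PPP1R15A (0.56) rose. Of 21 hypoxia response genes, 7 rose, 5 fell and 9 were not called, the same as adjusted over the list alone (camera adjusted p = 0.507), with P4HA2 (0.85) rising and DDIT4 (-1.89), an mTOR inhibitor, falling.

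Epithelial, mesenchymal and glandular genes moved in both directions. Of 26 epithelial genes, 11 rose, 6 fell and 9 were not called, the same as adjusted over the list alone (camera adjusted p = 0.401), with E-cadherin (CDH1) rising from 199 to 304 CPM and KRT8 (-0.40) and DSP (-0.47, a carrier of TGGTCAAA) falling. Of 22 mesenchymal genes, 7 rose, 5 fell and 10 were not called, the same as adjusted over the list alone (camera adjusted p = 0.663, direction higher). Their mean was 0.21 and their median -0.00, which turns positive with RLE, upper-quartile or library-size-only scaling (0.06 with the last). THBS1 (2.38), CTGF (2.13) and CYR61 (1.51) rose and TGFBI (-1.05) fell, and fry called the list higher (adjusted p = 0.00022). Of 18 endometrial gland and secretory genes, 7 rose, 5 fell and 6 were not called, the same as adjusted over the list alone (camera adjusted p = 0.511), with GPX3 (0.94), MUC16 (0.64) and SOX17 (0.55) rising and WFDC2 (-0.87) falling. Of 13 oestrogen response genes, 6 rose, 4 fell and 3 were not called, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.68), with a median of 0.26, a mean of 0.00 and a lower direction by fry, and CA12 fell by 1.30 on the log2 scale. Of 5 squamous markers tested among 14, 3 rose, 1 fell and 1 was not called, the same as adjusted over the list alone (camera adjusted p = 0.20), and KRT17 had 0, 1 and 3 counts in siNC and 11, 16 and 22 in siTCF19. Of 13 cilium genes, 2 fell, 0 rose and 11 were not called, the same as adjusted over the list alone (camera adjusted p = 0.284), FOXJ1 falling by 0.72 on the log2 scale.

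Of 11 NuRD subunits and UHRF2, a set of chromatin regulators, 6 fell, 1 rose and 4 were not called, the same as adjusted over the list alone (median -0.13, camera adjusted p = 0.0463). The deacetylase complex genes MTA1 (-0.38), MTA2 (-0.33), CHD4 (-0.32) and HDAC2 (-0.32, a carrier of GGTCAAA) fell, and UHRF2, a ubiquitin ligase, rose (0.17). The list had an adjusted p = 0.402 with an estimated correlation, in a range of 0.0281 to 0.402. It was not called with library-size-only scaling (0.09), with a filter of 1 CPM in 3 libraries (0.0539), without the 3' UTR word carriers (0.0762), with the trend removed (0.124), or without siNC replicate 1 (0.0713), siNC replicate 2 (0.0811), siTCF19 replicate 2 (0.0917) or siTCF19 replicate 3 (0.0703). Of 13 genes of the small RNA machinery, 4 fell, 1 rose and 8 were not called, the same as adjusted over the list alone (camera adjusted p = 0.381), with the Argonaute genes AGO1 (-0.66, a carrier of TGGTCAA) and AGO2 (-0.18) falling and TNRC6B (0.31) rising.

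Markers of other cell types gave no common direction. Of 7 endothelial markers tested among 14, 2 rose, 2 fell and 3 were not called, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.468), with EGFL7 (-0.88) falling. Of the 4 fibroblast markers tested, COL1A1 (0.58) rose, COL1A2 (-0.66) fell and 2 were not called, the same as adjusted over the list alone. None of the 3 leukocyte markers tested was called by edgeR, with or without adjustment over the list alone, and CD4 had 10.6 CPM in siNC and 12.1 CPM in siTCF19 (adjusted p = 0.25). Of 4 nuclear-retained and abundant non-coding RNAs tested, 2 fell and 2 were not called, or 1 rose and 2 fell adjusted over the list alone and at an unadjusted p under 0.05, while DESeq2 called 0 higher. RN7SL2 (-1.09), which has many copies, is uncertain, and NEAT1 (-0.36) was not called without siNC replicate 3 (-0.11, adjusted p = 0.414) or on the log2(FPKM + 1) scale (adjusted p = 0.235). These 3 last lists had fewer than the 5 tested members that the list test needed.

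**Figure D3:**
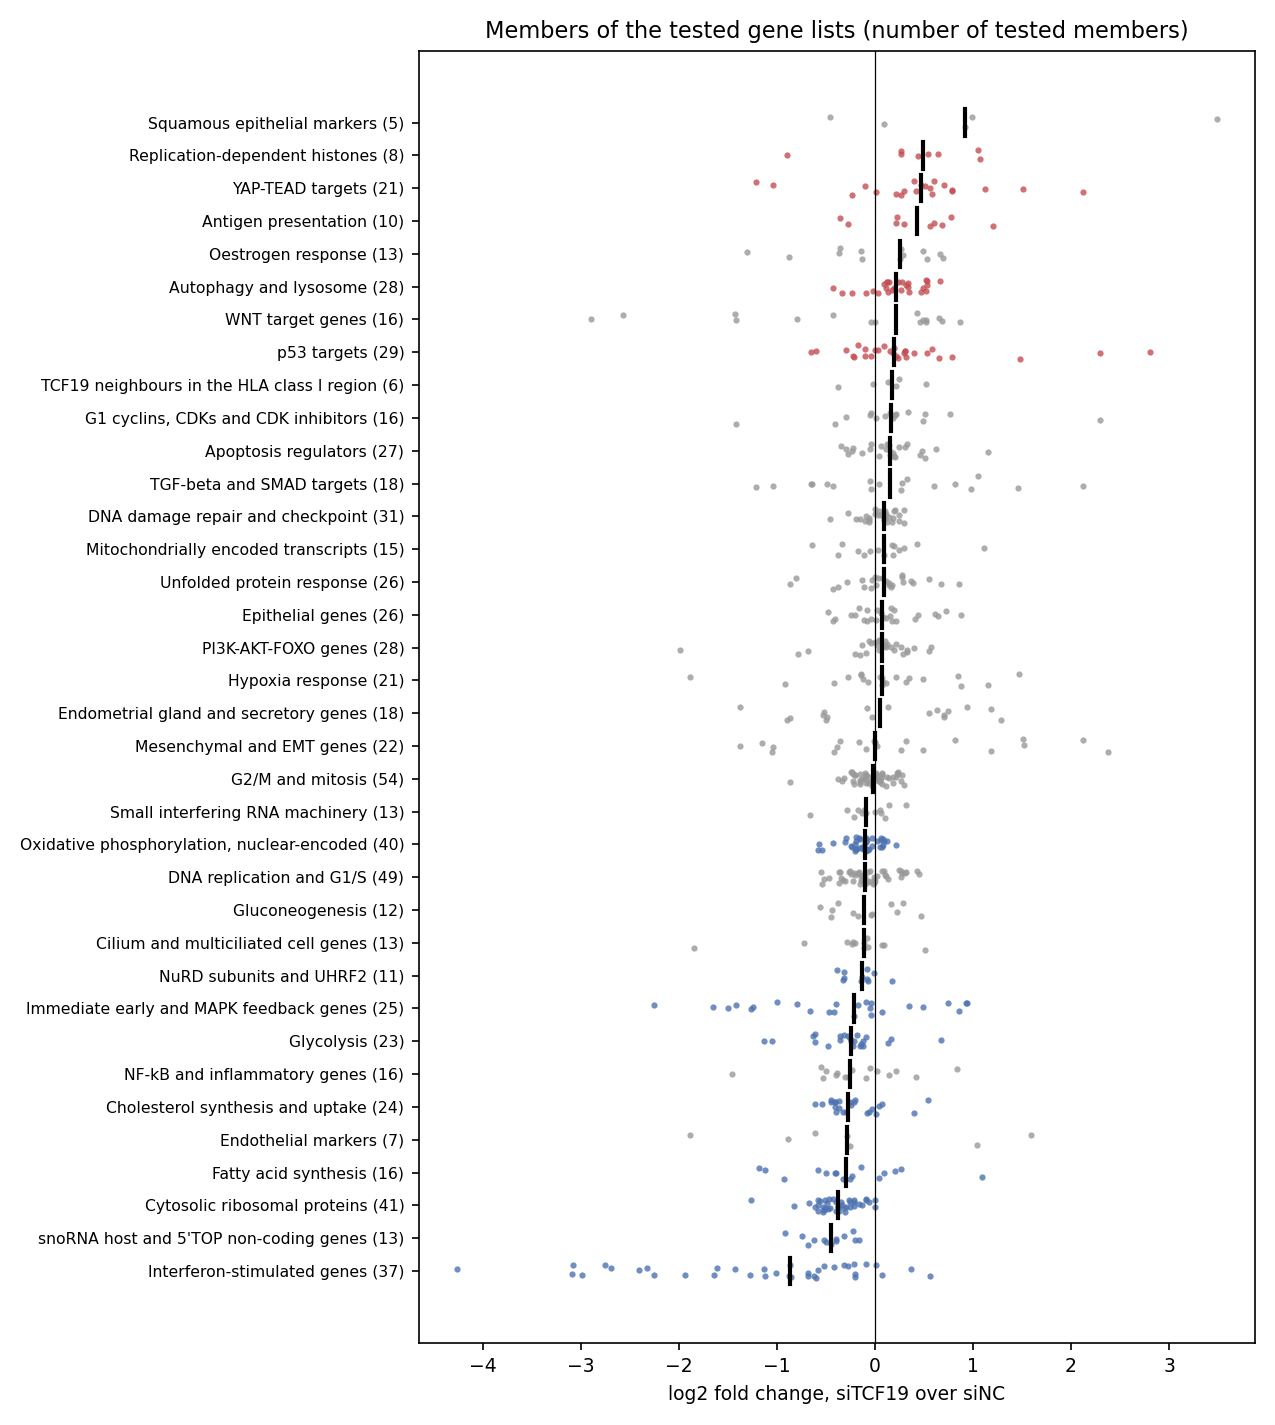
Log2 fold change of siTCF19 over siNC for the tested members of the 36 gene lists. Dots are genes, black bars the median of a list, and colour shows the camera call at the preset correlation, with 5 lists higher (red), 9 lower (blue) and the rest not called (grey).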

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

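The runs without genes carrying TGGTCAA or GGTCAAA and with the length and expression trend removed were chosen after the results were seen. No called result reversed its direction in any of the 21 settings, and 149 of the 156 called named genes kept their call in each of the 15 settings run on single genes that gave them a value, while 7 lost it in at least 1. CDH5, KRT17 and the squamous list had no value with a filter of 1 CPM in 3 libraries, nor had that list without the word carriers. TCF19 had a log2 fold change of -2.26 to -2.11. Called genes numbered 3198 to 3470 higher and 3087 to 3331 lower with 1 library left out, where fewer samples enter, and 2829 and 2929 by DESeq2. On the log2(FPKM + 1) scale, which pulls low genes toward 0 by construction, 83 genes were higher and 121 lower by at least 2-fold. The number of lists called higher was 3 with library-size-only scaling, 3 with no filter, 2 at an adjusted p under 0.01, 0 by camera with an estimated correlation (1 at an unadjusted p under 0.05) and 12 by fry, and 2 to 5 with 1 library left out (2 without siNC replicate 2, siTCF19 replicate 1 or siTCF19 replicate 3). The number called lower was 1 by camera with an estimated correlation and 15 by fry, and 7 to 9 with 1 library left out. Apart from the smaller number of samples and the other question fry asks, the cause was not tested. For interferon-stimulated genes and YAP-TEAD targets the estimated correlations were -0.00154 and -0.0113, below the preset 0.01. These values argue against a higher correlation among members as the cause of the weaker result for those lists. In the other called lists the estimate was above 0.01, from 0.0239 for fatty acid synthesis to 0.579 for ribosomal protein genes. Whether those correlations weakened the results was not tested. Fatty acid synthesis lost its call even at 0.0239 (adjusted p = 0.298 by camera with an estimated correlation). Of the 14 called lists, 9 lost the call at most with an estimated correlation. At this depth 95.2% of simulated 2-fold changes and 76.8% of 1.5-fold changes were recovered, so genes not called may still differ by less. The simulated changes were never placed in genes with the lowest counts, and such genes may differ by 2-fold or more without a call.

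With the replicate number as a block, 3433 genes were higher and 3441 lower, 468 and 377 by 2-fold, TCF19 kept its call, and 5 lists were higher and 8 lower, the NuRD list losing its call (adjusted p = 0.0721, in a range of 0.0281 to 0.402 over camera runs). No other call of a list or named gene changed with the block. The deviations of same-numbered libraries from their group means correlated at 0.0086, -0.0241 and 0.021 across genes, so the data show no pairing by number, and not every library correlated best with its own number.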

Other observations

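The gene families described here with their named members, the test of the 3' UTR words in random parts of the genes and the share of lower genes with neither word were chosen after the results were seen. Camera p-values of the families were adjusted over these added families only, not over the lists fixed in advance. The families were tested on the same values that were seen before they were chosen, so their p-values are not independent tests. Translation initiation and mitochondrial ribosomal protein genes were called lower as families. Of 54 translation initiation genes with EIF symbols, 31 fell and 5 rose (median log2 fold change -0.19, camera adjusted p = 0.000385, and adjusted p = 0.125 with an estimated correlation), with EIF4B (-0.63) and EIF3D (-0.56) falling and EIF2AK3 (0.70), a kinase of an initiation factor, rising. Of 77 mitochondrial ribosomal protein genes, 32 fell and 5 rose (median -0.13, camera adjusted p = 0.00089, and adjusted p = 0.227 with an estimated correlation), with MRPL3 at -0.87.

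Keratin and laminin chain genes were called higher as families, with adjustment over the added families only. The list of 26 epithelial genes, fixed in advance and adjusted over all tested lists, was not called (camera adjusted p = 0.401). The adjusted p-values of the families and of that list are therefore not directly comparable. Of 10 keratin genes, 6 rose and 2 fell (median 0.71, camera adjusted p = 0.0179, and adjusted p = 0.254 with an estimated correlation), KRT15 by 1.81 on the log2 scale. Of 9 laminin chain genes, 5 rose and 0 fell (median 0.28, camera adjusted p = 0.0179, and adjusted p = 0.168 with an estimated correlation), with LAMB3 (1.09) rising. Of 9 annexin genes, 7 rose and 1 fell, and the family was not called (camera adjusted p = 0.0582), nor were 477 zinc finger genes with ZNF symbols, of which 61 rose and 84 fell (camera adjusted p = 0.314).

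Genes lower by 2-fold in siTCF19 carried 2 overlapping words in their 3' UTRs more often than other genes. Of 289 such genes, 65 (22.5%) carry TGGTCAA or GGTCAAA, against 11.3% of other genes (odds ratio 2.28, one-sided Fisher's exact p = 7.17e-08), while 36 of 320 genes higher by 2-fold carry one (one-sided Fisher's exact p = 0.592). The words were picked for their tie to low fold changes in these same genes, so the p for the lower genes is not an independent test. Of all 7-base words, GGTCAAA was tied most strongly to lower expression (t = -10.05), and it is absent from TCF19 transcripts. TGGTCAA lies in coding exon 3 of TCF19 (chromosome 6, 31161453 to 31161459, within CAGCCAAGGTACTTTGGTCAAT). That match alone decides little, since 18.6% of the tested words occur in TCF19 transcripts. Mean log2 fold changes were adjusted for UTR length, composition and expression, and set against genes without GGTCAA. The difference was -0.23 with TGGTCAAA and -0.05 with GGTCAA only. It was -0.10 with TGGTCAA otherwise and -0.12 with GGTCAAA otherwise. A word ranked first in 1 random part of the genes was enriched among lower genes of the other part (odds ratios 2.09 and 2.97, one-sided Fisher's exact p = 0.00619 and 1.84e-06). An effect of the TCF19 siRNA through seed matches may therefore account for that excess. Of the lower genes 77.5% carry neither word, which does not bound a seed effect, since 6-base matches, sites outside the 3' UTR and genes lowered downstream of a carrier fall outside that count. For the higher genes no word passed the Bonferroni limit of the regression (lowest adjusted p = 0.587, with 501 words at an unadjusted p under 0.05). Fisher's exact test takes no account of UTR length or composition, and by it words were enriched among the higher genes too. CCCATCC was in 24.1% of genes higher by 2-fold and 13.5% of other genes (one-sided Fisher's exact p = 4.26e-07), with a regression effect of 0.05. For the lower genes as a whole, seed matches and a response to lower TCF19 cannot be told apart, since the sequence of the siRNA is not given in the sources used here.

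Interferon-stimulated genes were lower in siTCF19, with a median log2 fold change of -0.86. The tables argue against seed matches in these genes as the whole cause, since the 34 members without GGTCAAA had a median of -0.87 (-0.96 to -0.82 with 1 library left out), while an indirect seed effect through another gene was not tested. An interferon response raised by the control siRNA could give the same difference, and the NF-kB and inflammatory list, at a median of -0.25, does not decide it. That explanation and a fall after loss of TCF19 cannot be told apart, since no untransfected library was analysed here.

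Ribosomal protein genes were lower, with a median log2 fold change of -0.38. These genes are short and highly expressed, and a trend of the fold change with length and expression, fitted without them, left a median of -0.27 once removed (-0.30 to -0.21 with 1 library left out), so that trend may account for part of the shift but not for all of it. The scaling of the libraries was not the whole cause either, since the median nearest 0 under any scaling was -0.32 (library size only, -0.35 to -0.28 with 1 library left out). A response to lower TCF19 stays open as a hypothesis, and the pseudogenes that can share reads with these genes were not tested.

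The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 3586 genes higher and 3597 lower, 464 and 375 by 2-fold, and for each of these 4 counts it was 1 split of 10 with as many. Every other split called 0 genes by edgeR. The most genes at an unadjusted p under 0.05 in another split was 307, and the most DESeq2 calls, in a different split, was 2. Each other split mixes siNC and siTCF19 libraries on both sides, so the knockdown difference enters its spread. Few gene calls there follow from that design and do not measure what chance alone gives. A split and its mirror are the same split, so lists called in either direction were set against the real counts. On that basis 3 of 10 splits gave as many as the real 5 lists higher, and 1 of 10 as many as the real 9 lower (highest other 6 lists in one direction for both). Of the 9 other splits, 8 called at least 1 list. The other splits keep part of the real difference, so their lists are no measure of chance either.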
